A study of Homo sapiens with 2 samples.

How the data were processed

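Total RNA of A375 cells at 0 Gy and 8 Gy was extracted with TransZol and made into libraries with an mRNA-Seq kit, per the labels' protocols, with 1 library per dose. No time after irradiation is given in the sources used here. The submitters' processing notes name only a mouse genome build, mm10, although the cells are human. The identifiers in the table are human: of 1928 RefSeq identifiers 1866 were in the human RefSeq gene table, and of 1648 Ensembl transcripts 1337 were in GENCODE 29 with the same version and 1545 with the version ignored. The aligner, the counting method, the strand setting and the test are not given in the sources used here, so reads of overlapping and antisense genes may not be separated. No genome coordinates are printed, because no human build is named.

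The table holds, per the file headers, a log2 fold change, a p-value and a q-value for each RNA, computed by the authors by a method that the headers do not name. It also holds 2 columns of per-sample values whose names match neither sample's labels; these 2 columns were not used here. The labels do not show that they are these samples. Which library is in the numerator of the log2 fold change deposited by the authors could not be tied to a dose by any label, and was not inferred from the values.

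The most frequent log2 fold change, 0.14, occurs in 66 RNAs. Taking it as the value of equal read numbers in both libraries, each log2 fold change was searched for the smallest pair of whole numbers up to 3000 whose ratio gives it, within a relative tolerance of 1.5e-09. A pair was found for 3535 RNAs (98.9%) and not for 41, among them 15 of the 30 with q under 0.05. The true reads may be any whole multiple of the pair, so exact (Clopper-Pearson) 95% intervals from it are the widest that the reads allow. The denominator of the pair is 1 in 219 RNAs and the numerator in 150, and how 0 reads were treated is not given in the sources used here, so a 1 may stand for 0. Among 3541 simulated values, 100% of the pairs with smallest whole numbers up to 3000 were recovered exactly, and larger pairs were left out of that share. Of random values 0.35% were given a pair. This step was devised after the data were seen.

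The fold threshold of 2, 12 gene lists and the rule for named RNAs were fixed before the data were examined. The lists are p53-induced, DNA-damage, melanoma, snoRNA-host, microRNA-host, inflammatory and interferon, hypoxia and stress lncRNAs, abundant structural RNAs, rRNAs, and markers of fibroblasts and endothelium, blood, and epithelium. A list's median, with 1 value per symbol, was placed among 10000 random lists of the same size, for lists with at least 3 members listed. The plan matched random lists on mean expression, and RNA class was used instead because expression per library was not used here. Simulated lists of 10 RNAs shifted by 1 on the log2 scale lay above the central 95% of random lists in 20 of 20 cases, and 6 of 100 unshifted lists lay outside that central 95%. A first run of the unshifted check, with fewer lists, had more of them outside, and the number was raised to 100 to measure that share better.

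The rule named PURPL, the 5 most abundant RNAs, the 10 highest and 10 lowest ratios among RNAs with 50 reads in 1 library and a symbol other than an identifier or clone name (such as LOC numbers), and the 4 most abundant members of each list. Without abundances, the smallest read pair stood in for the 50 reads, and RNAs with q under 0.05 in the authors' deposited table and members of each list were named in place of the most abundant ones. These replacements, and which of those RNAs to name, were chosen after the values were seen. The test planned for counts was not run, since no counts were used.

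Bootstrap intervals of class medians used 2000 draws of RNAs and describe these libraries only. Alternatives were scaling to the median of all RNAs, a 4-fold threshold, read minimums of 10 and 50, 1 value per symbol, and leaving out intronic and precursor classes. Positions of precursors within host genes, transcript lengths and U1 sequences came from GENCODE 29. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, biopython 1.88 and matplotlib 3.10.9.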

Results

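Non-coding RNAs were profiled by RNA sequencing in A375 cells, an established human melanoma line, without irradiation (0 Gy) and after 8 Gy of ionizing radiation, with 1 library per dose. The stated question was how melanoma cells come to resist radiation, and the lncRNA named in the title of the series is PURPL. The authors' deposited table set 1 library against the other for 3576 RNAs under 3359 gene symbols, as a log2 fold change with a p-value and a q-value. Its column names match neither sample's labels. Whether its libraries are these samples, and if so which is the 8 Gy one, is therefore not given in the sources used here, and this limit applies to every fold change below. The libraries are therefore called the numerator and the denominator library, and no direction relative to dose is drawn. Total reads per library are unknown here. The fold changes themselves placed 3535 of the 3576 RNAs (98.9%) on ratios of whole read numbers, which gave the smallest read pair behind each value and a depth ratio of 1.10, with the denominator library the deeper one. Each interval below is an exact (Clopper-Pearson) 95% interval on that pair. It covers counting error only, since reads amplified by PCR without molecular identifiers are not independent molecules. There are no replicates, so no difference has a replicate check, and a p-value of the authors' deposited table compares these libraries, not the doses.

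PURPL, a p53-induced lncRNA listed under its older symbol LINC01021 (NR_038848.1), was 4.11-fold higher in the numerator library (95% interval 3.40 to 4.98), from at least 527 reads against 141. In the authors' deposited table its log2 fold change is 2.04, with p = 3.41e-06 and q = 0.00157. MIR34AHG, the host transcript of the p53-activated microRNA miR-34a, was 3.51-fold higher (3.24 to 3.81), from at least 2473 reads against 774. NEAT1, the architectural RNA of nuclear paraspeckles, was 2.47-fold higher (1.81 to 3.39). Among the 30 RNAs with q under 0.05 in the authors' deposited table, PURPL was the only long non-coding RNA, and MIR34AHG had q = 0.149 there. Those q-values do not follow the smallest read pairs. MIR4712, from a pair of 154 against 81, is among the 30, whereas a non-coding transcript of SERPINE2, from 167 against 91, is not. Being the only lncRNA there thus says little about how PURPL ranks among lncRNAs.

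Of 14 p53-induced lncRNAs fixed beforehand, 9 were in the table and all 9 had a log2 fold change above 0, 4 of them at 2-fold or more. The median of the 9 was 0.84, at percentile 99.6 of 10000 random lists of the same size and RNA classes, whose central 95% of medians ran from -0.29 to 0.60. LNCTAM34A, antisense to the miR-34a locus and listed as LINC01759, stood at 2.31-fold (1.04 to 5.49), and LINC-PINT, a p53-regulated RNA, at 1.79-fold (1.08 to 3.01). The strand setting is not given, so the value of LNCTAM34A may include reads of MIR34AHG. These members of the list may therefore not be independent, whereas the percentile counts them separately. PVT1, the lncRNA beside MYC, stood at 1.77-fold (1.55 to 2.02), TP53TG1 at 1.29-fold (1.03 to 1.63) and NORAD, an RNA induced by DNA damage that binds PUMILIO proteins, at 1.17-fold. LINC00346 stood at 1.03-fold, with an interval (0.611 to 1.74) on both sides of 1. The median over all RNAs was 0.16 on the log2 scale. Relative to it, 8 of the 9 lay above 0 and LINC00346 lay below.

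**Figure D1:**
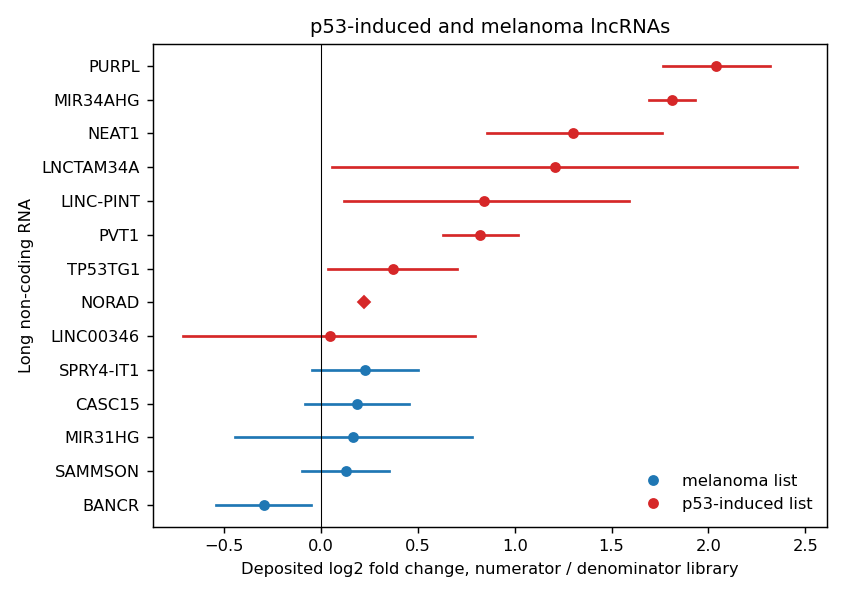
Deposited log2 fold change (numerator over denominator library) of the listed p53-induced (red) and melanoma (blue) lncRNAs, with lines for the exact 95% counting interval; the diamond (NORAD) has no interval because no read pair was recovered. The p53-induced RNAs run from 0.05 to 2.04 and the melanoma RNAs from -0.30 to 0.23.

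The lncRNAs tied to melanoma differed little between the libraries. Of 16 on that list, 5 were present and 4 had a value above 0, with a median of 0.17 (percentile 60.4), or 0.0016 relative to the median of all RNAs. SAMMSON, a lineage-restricted RNA that melanoma cells need to survive, stood at 1.09-fold (0.936 to 1.27), SPRY4-IT1 at 1.17-fold (0.967 to 1.42) and CASC15 at 1.14-fold (0.943 to 1.37). MIR31HG stood at 1.12-fold (0.734 to 1.71). BANCR, first described as a BRAF-activated RNA, was lower at 0.815-fold (0.687 to 0.964).

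DNA-damage lncRNAs went both ways: 6 of 15 were listed, 4 above 0 and 2 below, with a median of 0.14 (percentile 54.3) that becomes -0.029 relative to the median of all RNAs. CRNDE, a lncRNA raised in several tumours, was 3.23-fold higher (1.86 to 5.87), while LINP1, which takes part in non-homologous end joining, stood at 0.534-fold (0.280 to 0.978). DLEU2 stood at 0.951-fold (0.803 to 1.12). Hypoxia and stress lncRNAs had 6 of 7 listed members above 0, with a median of 0.20 (percentile 66.0), or 0.037 after median scaling. CYTOR was 1.76-fold higher (1.21 to 2.58) and MIR210HG, the host of the hypoxia-induced miR-210, stood at 1.15-fold (0.804 to 1.65). Inflammatory and interferon lncRNAs had 4 of 7 above 0 and a median of 0.05 (percentile 41.3), which becomes -0.11 after median scaling. NKILA, an inhibitor of NF-kB signalling, stood at 0.920-fold (0.853 to 0.992) and PACERR, which lies beside the PTGS2 promoter, at 1.35-fold (0.844 to 2.17).

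Of 37 names of genes whose transcripts host snoRNAs, in which GAS5 and DANCR also stand as SNHG2 and SNHG13, 22 genes were listed. Of these 22, 20 had a value below 0, whereas 58.4% of the RNAs classed as lncRNA had a value above 0. The median of the hosts, -0.08 (percentile 8.28), lay within the central 95% of random medians (-0.14 to 0.39), and it becomes -0.24 after median scaling, with 1 host above 0. The deposited p-values are largest near a log2 fold change of -0.14, and the median of the hosts lies above that value. The direction of the hosts therefore depends on the value taken as no change. SNHG19 stood at 0.916-fold (0.865 to 0.970), SNHG7 at 0.857-fold (0.770 to 0.954) and 0.898-fold (0.811 to 0.994) in its 2 listed transcripts, and SNHG8 at 0.986-fold (0.922 to 1.06). SNHG9 was the only one at 2-fold or more, at 0.466-fold (0.230 to 0.895). Hosts of microRNAs had 8 of 10 listed members above 0 and a median of 0.18 (percentile 65.2), or 0.017 after median scaling. MIR34AHG led them, MIR181A1HG stood at 1.72-fold (1.31 to 2.26) and MIR17HG, host of an oncogenic microRNA cluster, at 1.09-fold (0.910 to 1.31).

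Markers of other cell sources were few. Of the fibroblast and endothelial list 1 of 11 was present, MIR503HG, with a log2 fold change of 0.04 in the authors' deposited table. Of the epithelial list 2 of 9 were present, TINCR at 0.12 and LINC00511 at -0.10 in the authors' deposited table. None of 10 blood markers and none of 11 ribosomal or mitochondrial rRNAs was listed.

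Precursors of microRNAs were 304 of the 3576 RNAs. They made up 7 of the 30 RNAs with q under 0.05 in the authors' deposited table, all 7 higher in the numerator library. Since those q-values do not follow the smallest read pairs, this share says little about precursors as a class. MIR3189, inside GDF15, a gene of the p53 and stress responses, was 14.9-fold higher (6.10 to 47.5), from at least 68 reads against 5. MIR1204 and MIR1206, both inside PVT1, were 7.36-fold (3.76 to 16.0) and 12.1-fold (1.76 to 520.1) higher. MIR630, inside ARIH1, was 5.26-fold higher (2.93 to 10.1), MIR548AR, inside CDC16, 3.80-fold (2.02 to 7.68) and MIR4712, inside GABPB1-AS1, 2.09-fold (1.59 to 2.77). MIR3120, inside DNM3, has a log2 fold change of 4.80 in the authors' deposited table and no recovered read pair. The 5 other precursors with no pair, MIR320D1, MIR548N, MIR4637, MIR491 and MIR556, lie between 3.33 and 3.93 in the authors' deposited table, and a value filled in for 0 reads in the denominator library is not excluded for these 6. Likewise, the 1 read behind MIR1206 in that library can stand for 0. In the other direction, MIR25, inside the replication gene MCM7, was 3.27-fold lower (2.02 to 5.51). The precursors placed inside a gene here lie on the strand of that gene in GENCODE 29, so reads of the host's unspliced RNA cannot be told from reads of the precursor.

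Small structural RNAs supplied most other low q-values, and 17 of the 30 RNAs with q under 0.05 in the authors' deposited table, all of them of this kind, differed by less than 2-fold. RN7SK, which holds the elongation factor P-TEFb inactive, was 1.20-fold lower in the numerator library, and RMRP and RPPH1, the RNA parts of RNase MRP and RNase P, were 1.17-fold and 1.21-fold lower. SNORD3A, the U3 RNA of ribosome processing, was 1.37-fold higher and RNY4, a Y RNA, 1.61-fold higher (1.33 to 1.96). SNORA73B was 1.42-fold lower (1.32 to 1.52) and SNORD43 2.32-fold lower (1.69 to 3.20). Positions of snoRNAs within host genes were not examined, so reads of unspliced host RNA may be included in their values. On the structural list fixed beforehand 27 of 29 RNAs were present, 11 above and 16 below 0, with a median of -0.11 (percentile 33.7), which becomes -0.28 with 5 above 0 after median scaling. Of the list, 10 had q under 0.05 in the authors' deposited table.

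Genes for U1, the snRNA that pairs with the 5' splice site, stood at opposite ends. In the authors' deposited table RNU1-2 stands at a log2 fold change of 2.06 and RNVU1-18 at 1.99, whereas RNU1-1 stands at -2.81, RNU1-4 at -0.71 and RNVU1-7 at -5.17. RNU1-3 stands at 0.04 in the authors' deposited table. These 6 copies are at least 99% identical to another listed copy, and all but RNVU1-7 are 100% identical to one. Reads of identical copies cannot be told apart, so their individual values cannot be read as those of separate genes. The value of RNVU1-7 is uncertain as well. The 3 copies under 95% identity, RNVU1-14, RNVU1-15 and RNVU1-6, lay between -0.17 and -0.03 in the authors' deposited table.

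**Figure D2:**
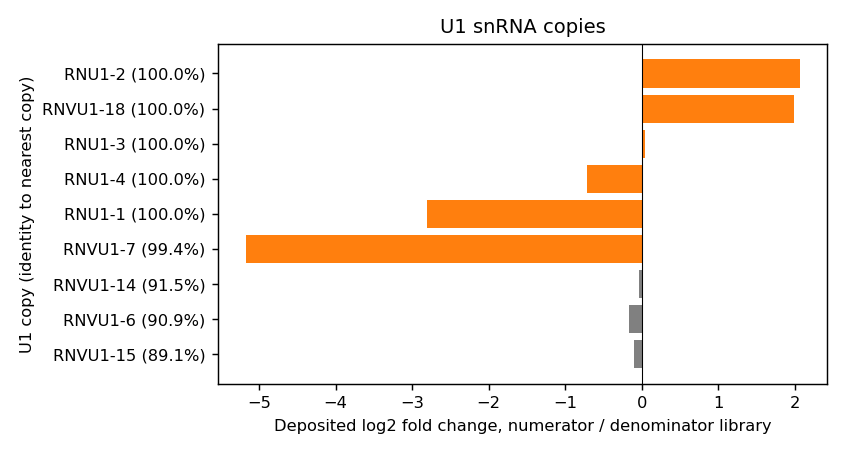
Deposited log2 fold change (numerator over denominator library) of 9 U1 snRNA copies, 1 bar per copy, with percent identity to the nearest other listed copy in brackets. Copies at 99% identity or more (orange) run from -5.17 to 2.06, and the more divergent copies (grey) from -0.17 to -0.03.

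Over all RNAs, 583 were at least 2-fold higher in the numerator library and 227 at least 2-fold lower, so that 72.0% of these were higher. Scaling to the median of all RNAs gave 467 and 293, or 61.4% higher. Among RNAs with a smallest read pair of 50 or more the numbers were 111 and 11, without the 41 RNAs that have no recovered pair. The authors' deposited table gives 30 RNAs with q under 0.05, 18 higher and 12 lower, of which 13 differed by 2-fold or more, and 3508 RNAs with q equal to 1. Higher and lower here are taken from a log2 fold change of 0. The deposited p-values are instead largest near -0.14, so the test behind them appears not to take 0 as no change. RN7SL1 (-0.11), RN7SL2 (-0.07) and RNU4-1 (-0.013) are counted as lower but lie above that value.

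The size of the difference varied with RNA class. Sense-intronic RNAs, transcribed within introns of other genes, had a median of 0.62 (bootstrap 95% interval over RNAs 0.44 to 0.75), with 57 of 193 at least 2-fold higher and 6 at least 2-fold lower. Sense-overlapping RNAs had a median of 0.65 (0.28 to 1.02, 41 RNAs), microRNA precursors 0.40 (0.14 to 0.70, 304 RNAs) and lincRNAs 0.30 (0.22 to 0.37, 645 RNAs). Antisense RNAs lay lower at 0.07 (0.0040 to 0.14, 678 RNAs), and so did RNAs classed as lncRNA at 0.11 (0.07 to 0.14, 798 RNAs), both below the median of all RNAs. The lincRNA, antisense, sense-intronic and sense-overlapping classes hold Ensembl identifiers, whereas the lncRNA class holds RefSeq ones. The medians of lncRNAs and lincRNAs thus come from different annotation sources, and do not by themselves compare kinds of RNA. For snoRNAs the median was 0.0016 (-0.06 to 0.05, 274 RNAs) and for snRNAs -0.03 (-0.18 to 0.06, 27 RNAs). With a smallest read pair of 50 or more, the medians of sense-intronic RNAs and lincRNAs came closer, at 0.40 (52 RNAs) and 0.29 (213 RNAs). Under the same minimum microRNA precursors had a median of 0.24 over only 13 RNAs, and antisense RNAs 0.017 over 175.

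**Figure D3:**
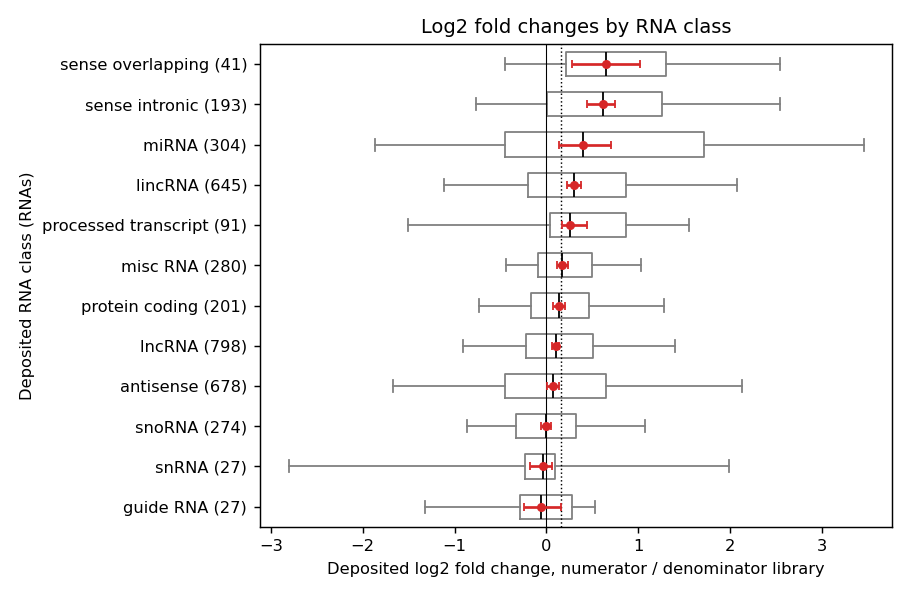
Deposited log2 fold change (numerator over denominator library) by RNA class for classes of 10 or more RNAs; boxes show quartiles, whiskers percentiles 5 to 95, red points the median with its bootstrap 95% interval, and the dotted line the median of all RNAs, 0.16. Sense-overlapping (0.65) and sense-intronic (0.62) RNAs have the highest medians.

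Among 796 RNAs with a smallest read pair of at least 50 and a gene symbol that is not an identifier or clone name, the 10 highest were MIR3189, MIR1204, TGFA-IT1, MIR630, PURPL, LHFPL3-AS1, USP6NL, MIR34AHG, CRNDE and HSP90B2P. TGFA-IT1, an intronic transcript of the growth factor gene TGFA, was 6.10-fold higher in the numerator library (2.97 to 14.1) and LHFPL3-AS1 3.82-fold higher (2.38 to 6.37). A non-coding transcript of USP6NL was 3.69-fold higher (2.34 to 6.02) and the pseudogene HSP90B2P 3.20-fold higher (2.16 to 4.84). The 10 lowest were RNVU1-7, GUSBP9, MIR25, LINC01970, SNORD43, HTRA2, PI4KAP1, LINC00920, SNORD58A and OR51B5. GUSBP9, a pseudogene of the lysosomal enzyme GUSB, was 8.04-fold lower (5.21 to 13.0) and LINC01970 2.64-fold lower (1.59 to 4.57). A non-coding transcript of HTRA2, which encodes a mitochondrial protease, was 2.02-fold lower (1.21 to 3.46), and PI4KAP1 and LINC00920 were each 1.77-fold lower (1.24 to 2.55). Pseudogenes such as GUSBP9, HSP90B2P and PI4KAP1 share sequence with their parent genes, so their values are uncertain. Of 634 RNAs left out for such a name, 14 had ratios above HSP90B2P and 14 below OR51B5, among the former LOC440910 at 4.50-fold, named here after its value was seen. The ranking also leaves out the 41 RNAs with no recovered read pair, of which 8 were at least 2-fold higher and 1 at least 2-fold lower. These include RNU1-2, RNVU1-18 and MIR3120 on the higher side and RNU1-1 on the lower.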

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

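The read minimums, the values per symbol or per transcript and the count without intronic and precursor classes were chosen after the data were seen. Of 29 alternative values 23 stayed within a fixed tolerance, 2 of them with a change of sign, and 6 moved beyond it. The tolerance was 1.5 times for a count, the counting interval for PURPL, and the SD of random lists of the same size for a list median, which is wider for shorter lists. A 4-fold threshold gave 180 RNAs higher and 56 lower in the numerator library, by its own construction. Requiring a smallest read pair of 50 or more gave 111 and 11, and a minimum of 10 gave 398 and 153. Scaling to the median of all RNAs moved the median of snoRNA hosts to -0.24 and of structural RNAs to -0.28, by the subtraction of 0.16, and left PURPL at 1.87 and the p53-induced list at 0.68. The same scaling moved every list median by the same amount, left the melanoma, microRNA-host and hypoxia medians at 0.0016, 0.017 and 0.037, and turned the small medians of the DNA-damage list to -0.029 and of the inflammatory list to -0.11. No paired analysis was possible because there is 1 library per dose. Scaling to the table total, the filters on low values, a larger pseudocount, scaling without the 10 most abundant RNAs and the most abundant transcript per symbol were planned and not run, since they need values per library. The depth limits RNAs with few reads most: MIR1206 rests on a pair of 11 against 1, where the 1 can stand for 0 reads, and its interval runs from 1.76-fold to 520.1-fold.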

Other observations

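Of the tests below, those on U1 copies, unspliced transcripts, deposited p-values and p53 target genes were chosen after the result was seen, as was the read minimum applied to the classes. The tests on precursor position and transcript length were not.

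Non-coding transcripts and precursors tied to protein-coding genes that p53 activates were also listed. A non-coding transcript of BAX, which opens the mitochondrial outer membrane in apoptosis, was 2.71-fold higher in the numerator library (1.45 to 5.31), and one of PHLDA3, an inhibitor of AKT, stood at 3.84-fold (0.732 to 37.9). MIR3191, on the strand of the apoptosis gene BBC3, was 4.67-fold higher (1.52 to 19.1), while MIR3190, on the opposite strand there, had a log2 fold change of -2.19 in the authors' deposited table, from a pair of 1 against 5, where the 1 can stand for 0 reads. One hypothesis is that p53 target genes as a class were higher in the numerator library. Of 45 such genes 5 transcripts or precursors were listed, with a median of 1.94 at percentile 98.8 of random sets of the same RNA classes. This may not be read as evidence, because the 45 genes were written down after 3 of the 5 values had been read.

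The precursors inside PVT1 all had higher ratios than PVT1 itself, at 1.77-fold. MIR1204 stood at 7.36-fold (3.76 to 16.0) and MIR1205 at 13.2-fold (1.95 to 563.5), while MIR1207 at 3.30-fold had an interval on both sides of 1 (0.265 to 173.0), the last 2 each on a denominator of 1 that can stand for 0 reads. MIR29A, which lies within LINC-PINT, has a log2 fold change of 3.46 in the authors' deposited table, from a pair of 10 against 1, where the 1 is not known to be a read. MIR93 lies with MIR25 inside MCM7, and its log2 fold change is -1.13 in the authors' deposited table. These RNAs, apart from MIR1204 and MIR25, were chosen after their values were seen.

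The 10 U1 copies had an SD of 2.13 in log2 fold change, against 0.98 for the other 17 snRNAs. A first test asked whether every copy is at least 95% identical to another. It failed on RNVU1-15 (89.1%), RNVU1-6 (90.9%) and RNVU1-14 (91.5%), and RNVU1-8 had no sequence to compare. The copies that failed lie near 0 and do not show the pattern, so the test decides nothing. A second test, added after that outcome, was restricted to near-identical copies: the 6 at 99% identity or more had an SD of 2.82, against 0.07 for the 3 under 95%. That test does not decide on uneven assignment of reads, because identities and fold changes were both known when it was written. The 6 copies also include the extreme values that prompted it. Without any test, RNU1-1, RNU1-2, RNU1-3, RNU1-4 and RNVU1-18 are each 100% identical to another listed copy. Their opposite values therefore cannot be read as those of separate genes. An effect of dose on U1 RNA stays open, since with 1 library per dose there is no spread between libraries to set it against. The values of identical copies cannot show such an effect on 1 copy.

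Sense-intronic RNAs lay above most other classes. Transcript length alone is argued against, since their median exceeded that of lincRNAs in each of 4 length quartiles, by 0.15 at the least, although the gap was also small (0.40 against 0.29) among RNAs with a read pair of 50 or more, so low values stay open in part. For more unspliced host transcript in the numerator library, 3 of the 3 sets tested had medians above that of all RNAs. These were retained-intron transcripts (0.33), sense-overlapping RNAs (0.65) and same-strand precursors (0.33). But precursors on the opposite strand (0.55, 19 RNAs) and those counted as outside genes (0.72, 27 RNAs) lay no lower. The precursors therefore give it no support, and it stays open. In placing precursors, a host gene named after the precursor itself was not counted as a gene. MIR222 and MIR100 were thus counted as outside genes, although MIR221 was placed inside MIR222HG and MIR125B1 inside MIR100HG. Some of the 27 may therefore lie inside genes. Genomic DNA carried into that library stays open too. The difference between same-strand precursors and those counted as outside genes was -0.39 (95% interval -1 to 0.46). An interval that includes 0 is what was written beforehand for this cause. The 27 precursors counted as outside genes were fewer than a minimum of 30, set before the result but not part of the written criterion. The test was therefore not taken to decide, and an effect of dose cannot be tested with 1 library per dose.

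The deposited p-values do not rank RNAs as the counting error of the recovered reads would. KCNQ1OT1 stood at 2.08-fold from at least 2355 reads against 1246, yet has p = 0.620 in the authors' deposited table, and MIR1206, from a pair of 11 against 1, has p = 0.000141 in the authors' deposited table. For 117 RNAs a deposited p above 0.05 stands beside an exact binomial p under 1e-06 on the smallest read pair. This argues against p-values that cover the counting error of these reads alone. A dispersion shared by all RNAs is argued against too: at the median SD that these 117 imply for a log2 ratio (1.03, normal approximation), 29 of the 30 RNAs with q under 0.05 have a deposited p below the smallest possible at any depth, and at the smallest SD 19 do. Both checks took a log2 fold change of 0 as no change, whereas the deposited p-values are largest near -0.14. Neither check was repeated from that value. Both also assume p-values computed from read numbers, which is not known. A test on other values, such as values scaled by transcript length, was not examined. A dispersion that falls with read number stays open because the pairs are minimum reads. Among the 30, it would need MIR4712, at 2.09-fold from a pair of 154 against 81, to have more reads than KCNQ1OT1. RNY4, at 1.61-fold from a pair of 269 against 183, would need the same. The test behind the deposited values is not given in the sources used here, and no biological explanation was tested for this pattern.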
